A study of Mus musculus with 12 samples.

How the data were processed

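The series holds 12 libraries of gonadal (peri-uterine) white adipose tissue from pregnant mice. Per the labels' protocols, total RNA was extracted with a column kit that included a DNase step, and libraries were made with a QuantSeq kit, which sequences the 3' ends of transcripts. Each count therefore stands for reads near a transcript's end, and no correction for gene length was made. Per the submitters' processing notes, the tools were BWA 0.7.12, SAMtools 1.3.1, TopHat2 2.1.1 and HTSeq 0.6.1, with the genome build mm10. The role of each tool, the gene annotation and the strand setting are not given in the sources used here. Reads of genes that overlap on opposite strands therefore cannot be told apart.

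The authors deposited raw read counts per gene in a table for each library, with 20632 gene symbols and no row without a gene name. Of these symbols, 4160 had a count of 0 in every library. Counts of Alas1, Igj, Pip5k1c, Smg6 and Tmem173 were multiples of 2 in all 12 libraries, and those of Gm715 multiples of 3; the cause is not given in the sources used here. Library totals ran from 5551970 to 12972700 counts. A count of 3 corresponds to between 0.231 and 0.540 CPM (counts scaled to a common library size) at these depths, and such limits cover counting error only.

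The labels place 4 libraries in each of 3 groups: wild type with vehicle (WT vehicle), knockout with vehicle (KO vehicle) and knockout with the treatment labelled Treg (KO Treg). The knockout label names Tnfrsf11a with Foxn1-Cre, and the wild type label names the same gene without Cre. The labels give each library its own number, taken here as 1 animal each. Replicate numbers follow accession order and pair nothing. The animal numbers fall into a lower and a higher series: all 4 KO vehicle animals are in the lower series, and WT vehicle and KO Treg hold 2 animals of each. The labels do not call these series a batch.

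Genes were kept by filterByExpr in edgeR 4.0.16, which left 12175. Counts were scaled by TMM and tested with the edgeR quasi-likelihood test (robust) in R 4.3.3, with the 3 groups in 1 fit and no covariate. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Values per group are CPM computed from the deposited counts on TMM-scaled totals, as mean ± SD over 4 animals. Log2 CPM used a prior count of 2. The standard error (SE) of a log2 fold change was its size divided by the square root of the F statistic.

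Before the data were examined, 42 gene lists, the tests, most alternatives and the rule for named genes were fixed. Of these lists, 37 had at least 4 tested members and were tested with camera in limma 3.58.1, with a preset correlation of 0.01 between genes; the other 5 were not tested. Camera with an estimated correlation, fry, and an exact permutation test of list means (70 arrangements, smallest two-sided p of 0.0286) were alternatives. The rule named Tnfrsf11a, Foxn1 and Foxp3 throughout. For each comparison it took up to 8 genes with the largest change in each direction, among genes past the threshold with groups that did not overlap and a mean of at least 5 CPM in the higher group. It also took up to 4 members, by smallest adjusted p, of each list that was called or held a called gene. Where fewer than 3 genes passed, it took the 5 genes of smallest p. The text names only some of the genes this rule gave, picked after their values were seen. Genes outside the rule are said to be chosen after their values were seen.

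Other alternatives were RLE and upper quartile scaling, DESeq2 1.42.0, limma voom with quality weights, other filters on low counts, fits of 2 groups, the number series as a covariate, the lower number series alone, thinned counts, a minimum log2 fold change of 1, a fit that was not robust, and leaving out each library. The contrasts that share the KO vehicle libraries were compared with 1000 resamples of residuals, and with all 6 splits of those libraries into pairs. Shares of opposite signs among picked genes were compared with 100 resamples. All 35 splits of the 8 libraries of each comparison were refitted on those 8 libraries alone, so their counts for the real grouping can differ from those of the fit of 12. Gene positions were taken from GENCODE M21 on GRCm38 (mm10).

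The fits were tested on simulated data for KO vehicle against WT vehicle, with 12175 genes and 200 changed genes in each of 5 draws. They found 58% of the genes changed 2-fold and 9.0% of those changed 1.5-fold, and 4.83% of the calls were wrong. With no change, at most 2 genes and 1 list were called. A list shifted by 0.5 on the log2 scale was called in all 5 draws. Genes were drawn independently, whereas the estimated correlation within the oxidative phosphorylation list was 0.653 in the real data. The simulated list counts therefore do not show how often camera calls lists of correlated genes by chance.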

Results

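Gene expression was measured by 3' RNA sequencing in the gonadal white fat of 12 pregnant mice at E17.5. The libraries fall into 3 groups of 4 animals: WT vehicle, KO vehicle, and KO Treg, the knockouts given the treatment labelled Treg. Totals ran from 5551970 to 12972700 counts in WT vehicle, from 8350350 to 9617500 in KO vehicle and from 6583260 to 8746950 in KO Treg. Libraries of 1 group (median correlation 0.970 across genes, which are not independent replicates) were about as alike as libraries of different groups (0.969), and every pair differed by more than sampling noise.

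Tnfrsf11a, which encodes RANK (chromosome 1, 105780718 to 105847981, mm10), had 44 to 90 counts in every library. Its level was 8.19 ± 2.51 CPM in WT vehicle, 7.60 ± 1.10 CPM in KO vehicle and 7.77 ± 1.92 CPM in KO Treg (mean ± SD, n = 4 each). These 3' reads from whole fat check nothing about a deletion by Foxn1-Cre, which acts in thymic epithelium. Foxn1 (chromosome 11, 78357577 to 78386558) had 0 counts in all 12 libraries. Foxp3, the transcription factor of regulatory T cells, had 0 counts in the 4 KO Treg libraries, 4 counts in KO vehicle 4 and 1 count in WT vehicle 4, too few to compare.

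The first comparison asked how the fat of knockouts given vehicle differed from that of wild types given vehicle. Htra3, a secreted serine protease, rose from 184 ± 7.97 CPM in WT vehicle to 447 ± 127 CPM in KO vehicle (log2 fold change 1.28 ± 0.19 SE, edgeR adjusted p = 0.0198). Tuba1a, an alpha-tubulin, rose from 249 ± 88.0 to 667 ± 88.4 CPM (1.42 ± 0.26, edgeR adjusted p = 0.0403). Fmo1, a flavin monooxygenase, was lower at 56.4 ± 4.22 against 101 ± 9.50 CPM (-0.84 ± 0.12, edgeR adjusted p = 0.0198). Ptger3, a prostaglandin E receptor, was also lower, at 106 ± 15.8 against 323 ± 96.7 CPM (-1.60 ± 0.30, edgeR adjusted p = 0.0447). Values are means ± SD with n = 4 animals per group. Reads of Tuba1a are uncertain because its exons overlap Gm49450 on the same strand. The call of Htra3 was lost without KO vehicle 1, KO vehicle 2 or WT vehicle 3, and that of Fmo1 without those or KO vehicle 4 (highest edgeR adjusted p = 0.0646 and 0.0731). The calls of Tuba1a and Ptger3 were lost without any KO vehicle library, KO Treg 3, KO Treg 4, WT vehicle 1 or WT vehicle 3, and that of Ptger3 also without WT vehicle 2 (highest 0.144 and 0.175).

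In all, 24 genes were higher and 10 lower in KO vehicle (34 of 12175, edgeR). A test of any difference among the 3 groups in the same fit called 4 genes. Groups did not overlap for any of the 34, nor for 792 of all tested genes, 6.51% where chance gives 2.86%. Other large increases were those of Zfyve28 (log2 fold change 2.62), Got1l1 (2.61), Dsn1 (1.55), Vgll3 (1.51), Hn1l (1.37) and Cdr2 (1.32). Got1l1 had 2 to 14 counts per WT vehicle library. Other decreases were those of Greb1, an estrogen-induced gene (-1.92), Bcat2, an enzyme of branched-chain amino acid breakdown (-1.21), Cpe, a carboxypeptidase (-1.02), Apoc1, an apolipoprotein (-0.94), Tmem38a (-0.91) and Sparcl1 (-0.73). Zfyve28, Greb1 and Bcat2 overlap exons of another gene on the opposite strand.

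Among called genes chosen after their values were seen, Pcolce2, a procollagen peptidase enhancer, had the smallest adjusted p (edgeR, 0.00732, log2 fold change 1.03), and Sod3 (0.99) and Mfge8 (0.89) were also higher. Cyp2f2 was called lower, with 1 or 2 counts per KO vehicle library and 12 to 36 per WT vehicle library. Its exons overlap another gene on the opposite strand. Lep, which encodes leptin, was at 262 ± 85.7 against 56.4 ± 43.6 CPM without passing (log2 fold change 2.21, edgeR adjusted p = 0.102, n = 4).

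**Figure D1:**
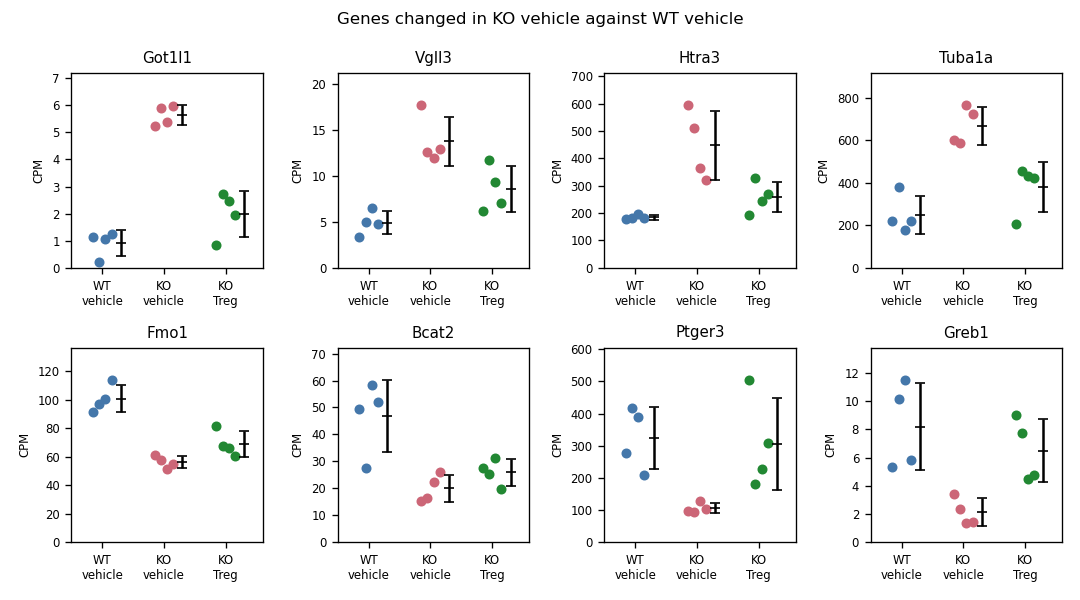
Expression in CPM (vertical axis) of 8 genes called between KO vehicle and WT vehicle, by group (horizontal axis); each point is 1 animal, and the bar beside the points is the mean ± SD (n = 4). The 4 KO vehicle animals lie above the 4 WT vehicle animals for Got1l1, Vgll3, Htra3 and Tuba1a, and below them for Fmo1, Bcat2, Ptger3 and Greb1.

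Among the fixed lists, 5 were called higher and 6 lower in KO vehicle by camera. Of these 11, only cell cycle had list means that did not overlap between the groups. It was also the only such list of all 37 tested, about the share of 2.86% that chance gives. Of 21 cell cycle genes, 16 had a fold change above 0 and 1 was called, or 2 when adjusted over the list alone. Cdk1, the mitotic kinase, rose from 4.71 ± 0.974 to 10.9 ± 2.41 CPM (edgeR adjusted p = 0.0403, n = 4). Its call was lost without any KO vehicle library, KO Treg 4, WT vehicle 1, WT vehicle 2 or WT vehicle 3 (highest edgeR adjusted p = 0.144). Of 21 genes of the unfolded protein response, 17 were above 0 and 0 were called, 0 also when adjusted over the list alone. Its chaperone Hspa5 was at 1647 ± 260 against 1101 ± 218 CPM (edgeR adjusted p = 0.157, n = 4). Camera gave an adjusted p of 0.000178 for cell cycle and 0.00374 for the unfolded protein response. With an estimated correlation the adjusted p was 0.499 and 0.560. With the mean of the fatty acid and triglyceride synthesis list as a covariate the unfolded protein response was not called (camera adjusted p = 0.129). This fit, those with Ucp1 as a covariate and those without the libraries with placental transcripts or Ucp1 were chosen after the data were seen. The synthesis list was itself called in this comparison and in KO Treg against KO vehicle (camera adjusted p = 2.74e-05 and 1.29e-06). Its use as a covariate can therefore remove part of the group difference, and a call that ends with it does not show a cause.

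Of 23 genes of fatty acid and triglyceride synthesis, 22 were below 0 in KO vehicle. Mlxipl, a carbohydrate-responsive transcription factor, was at 138 ± 32.2 against 276 ± 114 CPM (edgeR adjusted p = 0.146, n = 4). Exons of Mlxipl overlap another gene on the opposite strand. Fasn, fatty acid synthase, chosen after its values were seen, was at 558 to 12514 CPM within KO vehicle, highest in KO vehicle 3. Of 43 oxidative phosphorylation genes 42 were below 0, and of 12 smooth muscle genes 11 were. The mean log2 CPM of the smooth muscle list was 3.97 in WT vehicle 1, below all 4 KO vehicle libraries (4.40 to 5.61, highest in KO vehicle 4), and 6.14 to 6.95 in the other WT vehicle libraries. Its member Actg2, an actin of smooth muscle, chosen after its values were seen, was at 0.723 to 231 CPM within WT vehicle. No member of these 3 lists was called, 0 also when adjusted over the list alone. Camera gave an adjusted p of 2.74e-05, 2.64e-05 and 0.000290 for the 3 lists in that order. The adjusted p with an estimated correlation was 0.610, 0.644 and 0.560. With the fatty acid synthesis covariate oxidative phosphorylation was not called (camera adjusted p = 0.129), and the synthesis list, which is that covariate, turned to higher (0.999).

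Inflammatory cytokines and chemokines (8 of 12 above 0), macrophage genes (17 of 20), and immediate early and heat shock genes (13 of 21) were called higher as lists. Camera gave an adjusted p of 0.0197, 0.0282 and 0.0197 in that order. With an estimated correlation the adjusted p was 0.560, 0.641 and 0.560. Members called numbered 0 over all genes; adjusted over the list alone, 3, 1 and 4 were higher, and 1 immediate early gene was lower. Cxcl9, an interferon-induced chemokine, was at 77.3 ± 6.53 against 53.1 ± 2.15 CPM, and Cd68, a macrophage marker, at 38.5 ± 6.89 against 23.4 ± 3.18 CPM (edgeR adjusted p = 0.165 and 0.146, n = 4). The interferon response list was not called (15 of 22 below 0, camera adjusted p = 0.176). The inflammatory call was lost without KO vehicle 4, the immediate early call without KO vehicle 2, and the macrophage call without KO vehicle 1, KO vehicle 4, WT vehicle 1 or WT vehicle 4 (highest adjusted p = 0.130, 0.131 and 0.130). All 3 calls ended with the fatty acid synthesis covariate (camera adjusted p = 0.179, 0.179 and 0.228 in that order), and the macrophage call also without KO vehicle 1 and KO Treg 2 together, the libraries with placental transcripts (0.121). The macrophage mean of KO vehicle 3 was no higher than that of the lowest WT vehicle library (4.95 in both on the log2 CPM scale).

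Mast cell (5 of 6 below 0), skeletal muscle (7 of 9) and circadian clock genes (13 of 17) were called lower as lists. Camera gave an adjusted p of 0.0149, 0.0282 and 0.0197 in that order. The adjusted p with an estimated correlation was 0.499, 0.641 and 0.560. Members called numbered 0 over all genes, and 0, 1 and 1 were lower when adjusted over the list alone. The mast cell call was lost without KO vehicle 3, the clock call without WT vehicle 1, and the skeletal muscle call without KO vehicle 1, KO vehicle 3, WT vehicle 2 or WT vehicle 4 (highest adjusted p = 0.0625, 0.0967 and 0.212). The clock and skeletal muscle calls ended with the fatty acid synthesis covariate (camera adjusted p = 0.0816 and 0.0672). The clock call also ended without WT vehicle 1, KO vehicle 2 and KO vehicle 3, the 3 libraries with the most Ucp1 (0.103), and the skeletal muscle call without the placental libraries (0.109).

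The count of 34 genes fell to 0 with the number series as a covariate. It was also 0 within the lower series (2 WT vehicle, 4 KO vehicle). There all 34 genes kept their direction at an unadjusted edgeR p under 0.05. They were picked by small p in a fit that holds these animals, so this was likely in advance. The higher series holds no KO vehicle animal. The count was 1 without KO vehicle 1, KO vehicle 2 or WT vehicle 3, 2 without KO vehicle 4, 12 without WT vehicle 2, 13 without KO vehicle 3, 14 without KO Treg 4, 21 without KO Treg 3, 68 without KO Treg 1 and 125 without WT vehicle 4; DESeq2 called 250.

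The second comparison asked what the treatment labelled Treg changed within the knockout. Dysf, which encodes the membrane repair protein dysferlin (chromosome 6, 84008590 to 84211060), was lower in KO Treg, at 25.7 ± 5.24 against 52.5 ± 1.75 CPM (log2 fold change -1.03 ± 0.15 SE, edgeR adjusted p = 0.04997, n = 4). It was the single gene of 12175 past the threshold, and 1068 had an unadjusted p under 0.05 where 609 are expected. Its exons overlap those of Gm15475 and Gm33024 on the opposite strand. The genes next in p did not pass, each with an edgeR adjusted p of 0.248. Sec22b was at 64.9 ± 5.46 against 107 ± 12.5 CPM, Cdk1 at 4.71 ± 0.804 against 10.9 ± 2.41 CPM and Ppbp at 1.65 ± 0.540 against 4.82 ± 0.859 CPM (n = 4). Cyp2f2 had 7 to 21 counts per KO Treg library.

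Of 21 genes of the unfolded protein response, 20 had a fold change below 0 in KO Treg and 0 were called, or 8 when adjusted over the list alone (camera adjusted p = 3.11e-08). With an estimated correlation the adjusted p was 0.339. Of the 13 lists called in this comparison, only this list had means that did not overlap between the groups. The lipolysis list, not called (camera adjusted p = 0.126), did not overlap either (KO Treg up to 7.683, KO vehicle from 7.687 log2 CPM). These were the 2 lists without overlap among all 37 tested, where chance gives 2.86%. Hspa5 was at 995 ± 159 against 1647 ± 260 CPM, and Hsp90b1, another chaperone of the endoplasmic reticulum, at 397 ± 49.4 against 667 ± 166 CPM (edgeR adjusted p = 0.248 and 0.260, n = 4). Reads of Hsp90b1 are uncertain, since its exons overlap Gm15344 and Gm25745 on the same strand.

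Cell cycle (18 of 21 below 0), immediate early and heat shock (18 of 21), inflammatory cytokine and chemokine (10 of 12) and erythroid genes (5 of 5) were also called lower as lists. Camera gave an adjusted p of 0.000639, 0.00135, 0.00622 and 0.00501 in that order. The adjusted p with an estimated correlation was 0.339, 0.339, 0.488 and 0.488. Members lower when adjusted over the list alone numbered 1, 1, 2 and 2, against 0 over all genes. Ccl8, a monocyte-attracting chemokine, was at 11.8 ± 0.836 against 24.8 ± 10.9 CPM (edgeR adjusted p = 0.265, n = 4). All 4 calls ended with the fatty acid synthesis covariate (camera adjusted p = 0.0960, 0.0960, 0.213 and 0.213). On the log2 CPM scale the erythroid mean was 1.90 in KO vehicle 3, below 3 of the 4 KO Treg libraries, and 3.28 to 3.86 in the other KO vehicle libraries. The inflammatory mean of KO vehicle 3 (2.95) lay below that of KO Treg 3 (3.32).

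Fatty acid and triglyceride synthesis (20 of 23 above 0), oxidative phosphorylation (40 of 43) and circadian clock genes (12 of 17) were called higher as lists in KO Treg. Camera gave an adjusted p of 1.29e-06, 0.000305 and 0.00622 in that order. With an estimated correlation the adjusted p was 0.528, 0.681 and 0.339. Members higher when adjusted over the list alone numbered 0, 0 and 2, against 0 over all genes. Tef, a clock-controlled transcription factor, was at 327 ± 10.5 against 195 ± 25.2 CPM (edgeR adjusted p = 0.260, n = 4). Exons of Tef overlap another gene on the opposite strand. The oxidative phosphorylation call was lost without KO vehicle 1 (camera adjusted p = 0.188, the highest of 12 such fits) and without the placental libraries (0.242), and the mean of KO vehicle 3 (8.64 on the log2 CPM scale) lay above those of all 4 KO Treg libraries (8.38 to 8.54). With the fatty acid synthesis covariate the calls of oxidative phosphorylation and clock genes ended (0.713 and 0.0596), and the synthesis list turned to lower (0.943). Fasn, chosen after its values were seen, was at 2339 to 19198 CPM within KO Treg.

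T cell (9 of 10 below 0), macrophage (16 of 20), extracellular matrix (17 of 25), B and plasma cell (4 of 5) and fatty acid oxidation genes (21 of 23) were called lower as lists. Camera gave an adjusted p of 0.0185, 0.0253, 0.0362, 0.0435 and 0.04997 in that order. The adjusted p with an estimated correlation was 0.539, 0.539, 0.632, 0.488 and 0.681. Adjusted over the list alone, 1 matrix gene and 1 B and plasma cell gene were lower and 1 matrix gene was higher, against 0 over all genes. Of the fixed members, 10 of 23 T cell genes and 5 of 18 B and plasma cell genes were tested. No T cell gene was above 11.4 CPM in any library. Igj, whose counts were all multiples of 2, was among the B and plasma cell genes tested. The T cell call was lost without KO vehicle 4 or KO Treg 1 (highest adjusted p = 0.110), without the 3 Ucp1 libraries (0.121) and with the fatty acid synthesis covariate (0.0960). The T cell mean of KO vehicle 1 (0.69 on the log2 CPM scale) was no higher than that of the lowest KO Treg library (0.70, range to 1.19), and the other KO vehicle libraries were at 1.43 to 1.99. The macrophage call was lost without KO vehicle 1, KO vehicle 4, KO Treg 1 or KO Treg 2 (highest 0.216), without the placental libraries (0.417) and with the fatty acid synthesis covariate (0.290). The matrix call was lost without KO vehicle 1, KO Treg 1, KO Treg 2 or KO Treg 3 (highest 0.264) and without the placental libraries (0.344). The B and plasma cell call was lost without KO vehicle 2, KO vehicle 4, KO Treg 1 or KO Treg 4 (highest 0.116) and with no filter on low counts (0.0594). It also ended without the Ucp1 libraries (0.103), with Ucp1 as a covariate (0.0883) and with the fatty acid synthesis covariate (0.316).

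The fatty acid oxidation call was lost without KO vehicle 2, KO vehicle 3, WT vehicle 4 or any KO Treg library (highest adjusted p = 0.266), with no filter on low counts (0.0551), without the placental libraries (0.0554) and with the fatty acid synthesis covariate (0.152). Ucp1, the brown fat uncoupling protein, chosen after its values were seen, was at 778 and 216 CPM in KO vehicle 2 and KO vehicle 3, and all 14 thermogenic fat genes were below 0 without the list being called (camera adjusted p = 0.0523). Without the Ucp1 libraries the fatty acid oxidation list turned to higher (camera adjusted p = 0.441), and it was not called with Ucp1 (0.811) or the number series (0.469) as a covariate. Its mean in KO vehicle 4 (5.97 on the log2 CPM scale) lay below those of all 4 KO Treg libraries (6.06 to 6.30). The list of regulatory T cell genes was not called (7 of 11 below 0, camera adjusted p = 0.315), nor was that of cytotoxic T and NK cell genes (3 of 5, 0.982).

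**Figure D2:**
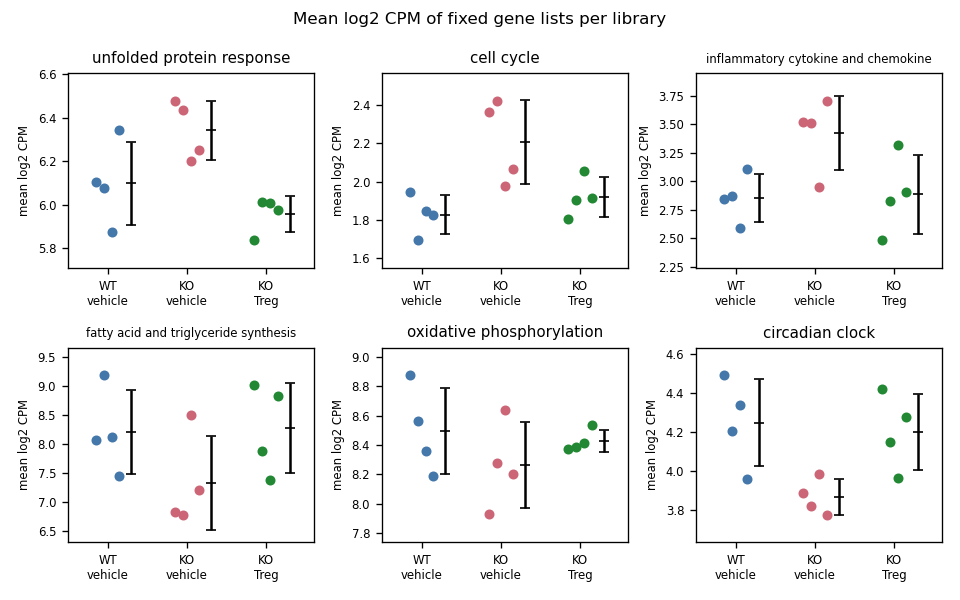
Mean log2 CPM over the tested members of 6 fixed lists (vertical axis) by group (horizontal axis); each point is 1 animal and the bar is the mean ± SD (n = 4). For the unfolded protein response the 4 KO Treg animals lie below the 4 KO vehicle animals, and fatty acid synthesis spans 6.78 to 8.50 within KO vehicle.

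The call of Dysf was lost when any of the 12 libraries was left out (edgeR adjusted p = 0.0622 to 0.280), with the number series as a covariate (0.145) and with RLE scaling (0.0567), and 0 genes passed within the lower number series. DESeq2 called 64 genes, 20 higher and 44 lower, and limma voom called 1.

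All 34 genes called in the first comparison, Htra3, Fmo1 and Ptger3 among them, had the opposite sign in the second, but both contain the KO vehicle libraries. With no effect, 34 genes picked by smallest p in the first comparison had the opposite sign in 90.4% of cases on average, and in all cases in 35 of 100 simulations. Over all genes the share was 76.8%, within the 95% range simulated with no effect (52.8% to 79.9%, mean 66.5%). A share as high came in 47 of 1000 simulations (one-sided resampling permutation p = 0.0480). Across all genes, which are not independent replicates, the covariance of the log2 fold changes was -0.100, against -0.0427 (95% range -0.0830 to -0.00774) in simulations with no effect, a difference of -0.0574. The correlation of -0.76 lay within the range simulated with no effect (-0.78 to -0.12, mean -0.49). With the KO vehicle libraries split into pairs, so that the contrasts shared none, the covariance averaged -0.0622 over 6 splits (-0.0740 to -0.0501; one-sided resampling permutation p = 0.00799, 1000 resamples). Of 34 genes picked with each pair, 88.2% to 97.1% had the opposite sign with the other pair, 92.2% on average over the 6 splits. Simulations with no effect gave 47.9% on average (95% range 9.03% to 75.7%), and 0 of 100 were as high (one-sided resampling permutation p = 0.00990, the smallest they can give). Splitting does not remove the number series. The KO vehicle animals are all in the lower series, while both other groups hold animals of each. The resamples had no series term, so these values do not tell the series from the group. Between the series, within groups, edgeR called 0 genes, a test that could miss weaker effects. Dysf was the only gene past the threshold in both comparisons with opposite signs, where 0.00279 are expected for independent lists, a value that leaves out the shared libraries.

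The third comparison set knockouts given the treatment labelled Treg against wild types given vehicle. No gene passed (0 of 12175 by edgeR and 0 by limma voom, 1 by DESeq2), and 349 had an unadjusted p under 0.05 where 609 are expected. The 5 genes of smallest p each had an edgeR adjusted p of 0.848. Ccl8 was at 11.8 ± 0.836 CPM in KO Treg against 31.0 ± 8.95 CPM in WT vehicle, Entpd5, a nucleotidase, at 56.2 ± 5.23 against 88.5 ± 13.1 CPM and Sun2, a nuclear envelope protein, at 128 ± 23.1 against 201 ± 17.0 CPM (n = 4). Ly6k was at 0.627 ± 0.111 against 2.95 ± 1.72 CPM and Tmem88b at 47.7 ± 7.45 against 29.6 ± 3.27 CPM (n = 4). Sun2 and Ly6k overlap exons of another gene on the opposite strand.

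Fatty acid oxidation (22 of 23 below 0), thermogenic fat (13 of 14), erythroid (5 of 5), unfolded protein response (17 of 21) and smooth muscle genes (11 of 12) were called lower as lists in KO Treg. Camera gave an adjusted p of 4.57e-06, 0.00207, 0.000258, 0.00559 and 0.00824 in that order. With an estimated correlation the adjusted p was 0.991 for all 5. The list means of the groups overlapped for each of the 5. No member was called over all genes, 0 also when adjusted over the list alone. Ucp1 was at 1966 CPM in WT vehicle 1 and at 0.539 to 47.3 CPM in the other WT vehicle libraries. The mean log2 CPM of smooth muscle genes was 3.97 in WT vehicle 1 and 3.88 in KO Treg 3, and 6.14 to 6.95 and 5.26 to 6.25 in the other libraries of these groups.

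Without WT vehicle 1 the calls of fatty acid oxidation and thermogenic genes were lost (camera adjusted p = 0.196 and 0.746, the highest of 12 such fits), that of smooth muscle genes without KO Treg 3, WT vehicle 2 or WT vehicle 3 (highest 0.440), and that of the unfolded protein response without KO Treg 1 or WT vehicle 4 (highest 0.291). Without the 3 libraries with the most Ucp1 the calls of fatty acid oxidation, thermogenic and unfolded protein response genes ended (0.246, 0.412 and 0.0539), and with Ucp1 as a covariate those of thermogenic and unfolded protein response genes did (0.546 and 0.0822). Within the lower number series 0 genes passed, and within the higher series, a fit chosen after the data were seen, 3 genes were lower (2 animals per group in each).

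**Figure D3:**
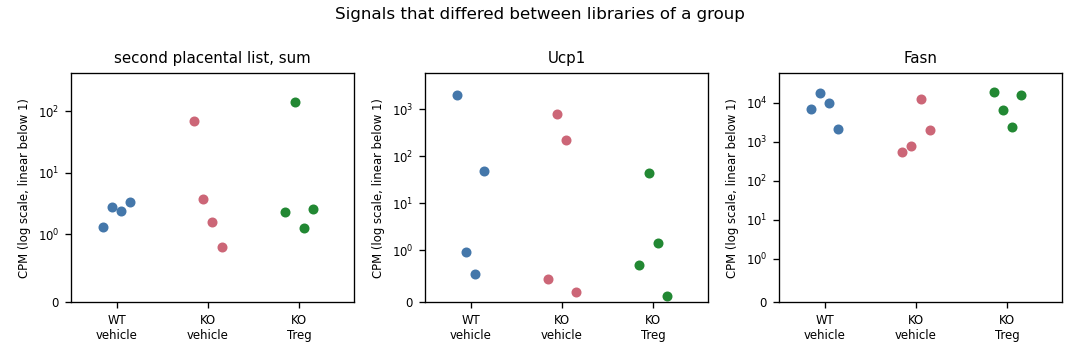
Summed CPM of 34 placental genes, and CPM of Ucp1 and Fasn (vertical axes, log scale that is linear below 1), by group (horizontal axis); each point is 1 animal (n = 4). The placental genes stand at 68.5 CPM in 1 KO vehicle animal and 140 CPM in 1 KO Treg animal, and at 3.72 CPM or less in the other 10.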

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

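The genes examined here were picked after their values were seen. Of 309 groups of 4 values (library totals, called lists and named genes, on the log2 scale for expression), 17 held 1 library far from the other 3, where chance gives about 15.4; the measure is the gap to the nearest library divided by the range of the group.

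Among list means, smooth muscle stood high in KO vehicle 4 (gap over range 0.928) and immediate early and heat shock genes high in KO Treg 2 (0.854). In KO vehicle, Zfyve28 was high in replicate 1 (0.853), Des high in replicate 4 (0.871), Lep low in replicate 2 (0.922), Cd2 low in replicate 1 (0.880), Entpd5 low in replicate 4 (0.836) and Sun2 low in replicate 1 (0.850). In WT vehicle, Got1l1 was low in replicate 2 (0.889), Lmod1 low in replicate 1 (0.914), Atp5j low in replicate 4 (0.844), Ccl8 high in replicate 3 (0.859) and Cd2 high in replicate 4 (0.931). In KO Treg, Tuba1a and Dysf were low in replicate 1 (0.911 and 0.897), Ppbp low in replicate 4 (0.845) and Dnajb9 low in replicate 2 (0.956). Des, Atp5j and Dnajb9 overlap exons of another gene on the opposite strand.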

How the results depend on the processing

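The fits without libraries with placental transcripts or Ucp1, with Ucp1 or the lipogenic list as a covariate, and with the higher number series alone were chosen after the data were seen. Unless a cause is named, the cause was not tested. No paired analysis was possible because the labels give no number shared between groups.

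For KO vehicle against WT vehicle, 34 genes became 250 with DESeq2, 0 with the number series as a covariate, 0 with the lower series alone (fewer animals), 3 without the 2 libraries with placental transcripts, 0 without the 3 libraries with the most Ucp1 (fewer animals in both) and 1 with the lipogenic list as a covariate. In each of these 6 fits all 34 genes had the same sign and an unadjusted p under 0.05. The 34 were picked by small p in a fit of the same libraries, so this was likely in advance. Leaving out 1 library gave 1 to 125, and the other settings 23 to 45. The single gene of KO Treg against KO vehicle became 64 with DESeq2. It became 0 with RLE factors, 2 groups in the fit, the series covariate, the lower series, a fit that was not robust, each of 4 settings chosen later and each library left out. For KO Treg against WT vehicle, 0 became 1 with DESeq2 and 3 with the higher series; leaving out 1 library gave 0.

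The 11, 13 and 5 called lists became 0 in each comparison with an estimated correlation, with fry and with exact permutation of list means. The permutation p cannot fall below 0.0286. After adjustment over 37 lists a call would need most lists at that floor, so its 0 was nearly fixed in advance. With the lipogenic covariate, itself a list called in both, the first and the second count became 4 and 3. Of these, 3 (mast cell, smooth muscle, cell cycle) and 2 (matrix, unfolded protein response) were among those called without it. With no filter on low counts the calls of B and plasma cell and fatty acid oxidation genes (second) ended (adjusted p = 0.0594 and 0.0551). Without the placental libraries the calls of macrophage (first and second), skeletal muscle (first), oxidative phosphorylation, matrix and fatty acid oxidation genes (second) ended. Without the Ucp1 libraries those of clock (first), T cell, B and plasma cell and fatty acid oxidation genes (second) ended, as did the last 2 with Ucp1 as a covariate. The third became 2 without the Ucp1 libraries and 3 with Ucp1 as a covariate. Leaving out 1 library gave 10 to 17 lists (17 without WT vehicle 4), 10 to 16 lists, and 3 to 9 lists (3 without WT vehicle 1, 9 without WT vehicle 3).

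The covariance of the contrasts was -0.0780 with the stricter filter, which tests fewer genes, and -0.131 with the series covariate; leaving out 1 library gave -0.132 to -0.0834. The count of genes past the threshold in both became 0 with RLE factors, the series covariate or any library left out. Tnfrsf11a lay near 0 and changed sign when 1 library was left out, with a log2 fold change of -0.31 to 0.038 for KO vehicle against WT vehicle, -0.13 to 0.17 for KO Treg against KO vehicle (-0.038 with voom) and -0.26 to 0.088 for KO Treg against WT vehicle. At this depth and number of animals, 9.0% of simulated 1.5-fold changes were found in KO vehicle against WT vehicle, so most changes of that size are missed.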

Other observations

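The tests of the number series, the lipogenic list and Ucp1 were chosen after their results were seen; those of the splits, the Foxn1 region and the second placental list were not.

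Placental genes, chosen after their values were seen, were read in the fat of 2 animals. Prl3b1, a placental lactogen, was at 9.58 CPM in KO vehicle 1 and 24.9 CPM in KO Treg 2, and at most at 0.750 CPM in the other 10 libraries. Tpbpa, a trophoblast gene, was at 12.5 and 38.3 CPM, and at most at 0.759 CPM in the others. Fasn varied within every group, from 2139 to 18120 CPM in WT vehicle, 558 to 12514 CPM in KO vehicle and 2339 to 19198 CPM in KO Treg. Ucp1 was at 1966 CPM in WT vehicle 1, 778 CPM in KO vehicle 2 and 216 CPM in KO vehicle 3, and at most at 47.3 CPM elsewhere.

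A candidate explanation for the placental transcripts is placental tissue, or its RNA, in those 2 samples. A second list of 34 placental genes, which shares none with the first, summed to 68.5 and 140 CPM there (601 and 1227 counts) and to at most 3.72 CPM in the others, a ratio of 18.4 for the lower of the 2. The test does not separate tissue carried over at dissection from reads of another library, and no biological explanation was tested. Without both libraries 3 genes were called between KO vehicle and WT vehicle.

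For the genes called between KO vehicle and WT vehicle, chance could not be excluded. The splits were fitted on the 8 libraries of a comparison, where the real grouping gave 45 genes, and not on all 12, where it gave 34. Of the 35 splits, 2 gave as many genes: 45 for the real split and 51 for that exchanging KO vehicle 3 and WT vehicle 4, with 0 genes in common. The number series and the lipogenic state of the animal could not be decided on. With each term the median log2 fold change of the 34 genes was 1.02 (quartiles 0.974 to 1.09) and 0.936 (0.830 to 0.984) of that without it. These genes were picked in the fit without the terms, and their groups did not overlap. Such picking favors genes that vary little within groups, so values near 1 were likely in advance. With the terms 0 and 1 calls were left as standard errors grew to 1.14 and 1.08 of their size. Between the series, within groups, edgeR called 0 genes (smallest adjusted p = 0.9997). An unadjusted p under 0.05 came for 331 genes where 609 are expected. Only WT vehicle and KO Treg, with 2 animals of each series, inform that test, so weaker series effects could be missed. Genes carried along with the Foxn1 locus are argued against as the source of most of the 34, with 0 of them within 10 Mb of Foxn1 where 0.805 are expected. That covers only genes near Foxn1 and would not bear on a Cre inserted elsewhere. The genotype, the number series, the lipogenic state and other differences between the animals stay open, and were not told apart from chance.

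For KO Treg against KO vehicle and against WT vehicle the real split called 0 genes in these fits (highest other 44 and 23), so all 35 splits have as many by construction and this count decides nothing. In the fits of 8 libraries the real groupings called 12, 16 and 5 lists, against 11, 13 and 5 in the fit of all 12. As many lists were called in 11 of 35 splits for KO vehicle against WT vehicle (real 12, highest other 17) and in 32 of 35 for KO Treg against WT vehicle (real 5, highest other 17; the split by number series called 9), so chance could not be excluded. For KO Treg against KO vehicle only the real split, 1 of 35, called as many lists (16, highest other 14). That share lay under the limit of 0.05 set beforehand. It is the smallest share that 35 splits can give, and 1 of 6 such counts, so chance stays open here too. No list of this comparison was called with an estimated correlation or fry (smallest adjusted p = 0.339 and 0.153), with 4 lists by the first at an unadjusted p under 0.05. None was called by exact permutation of list means either (smallest adjusted p = 0.264, 2 lists at an unadjusted p under 0.05). Its smallest possible p of 0.0286 made a call after adjustment nearly impossible.

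The lower fatty acid oxidation and thermogenic lists in KO Treg against WT vehicle may reflect brown adipocytes in single libraries such as WT vehicle 1. With Ucp1 as a term, and left out of the lists, the difference of the list mean was 0.456 and 0.227 of that without it. On the log2 scale it went from -0.42 to -0.19 ± 0.13 and from -0.93 to -0.21 ± 0.29 (SE). These spreads are too wide to decide, so brown adipocytes and a difference between the groups cannot be told apart.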
